A study of Mus musculus with 16 samples.

How the data were processed

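Total RNA from oocytes at the germinal vesicle (GV) stage and from eggs at metaphase of the second meiotic division (MII) of B6D2 mice was measured on 16 expression arrays. The mice were 6 weeks (young) or 66 weeks (old) of age. Per the labels, RNA was purified with the Picopure kit, turned into biotinylated cRNA with the small-sample target labelling assay of the array maker, and processed to signal values with MAS5. The version and settings of MAS5 are not given in the sources used here. Each of the 4 groups held 4 arrays, and samples were grouped by the stage, the age and the replicate number in their labels. The labels do not say whether the arrays of a group came from separate animals or separate pools, so every p-value here measures the spread between arrays only.

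The deposited table held the intensity of 45101 probe sets per array as MAS5 signal on a linear scale. The authors had scaled each array to a common target: the mean without the lowest and highest 2% of probe sets lay between 149.94 and 149.96 on the 16 arrays. Detection calls were not used here. Median signals of the arrays differed by 0.27 on the log2 scale, below the limit of 0.5 set for a further normalization, so the authors' scaling was kept. In GV oocytes the medians followed age, as given in the results. All columns of the table belonged to a sample, and no pair of arrays held identical values. For arrays, the number of arrays per group limits the precision of each mean.

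Signals were transformed to log2 after adding 6.5, the 20th percentile of all deposited values. The 64 control probe sets were set aside, and the upper 50% of the other probe sets by mean log2 signal over the 16 arrays was tested. This kept 22519 probe sets with a mean signal of at least 29.7, and 12040 genes. Of the 45101 probe sets, 34958 were assigned to 1 gene, 932 to several genes and 9211 to none in the annotation used here; 18194 genes were named in all. Chromosome positions were not used here.

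A model of 4 group means was fitted to each probe set over the 16 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a trend of the variance on the mean signal (12 residual degrees of freedom). The contrasts were old against young GV oocytes, old against young MII eggs, the difference between these 2 age effects, and MII eggs against GV oocytes in young and in old mice. P-values were adjusted by the method of Benjamini and Hochberg over the 22519 probe sets within each contrast, and probe sets with an adjusted p under 0.05 were taken as changed. Fold changes are those of signal plus 6.5, so where the signal of a group is low the fold and its rank depend on this constant. Values after ± are standard errors (SE) of log2 changes or standard deviations (SD) of signals over the 4 arrays of a group, as stated. All adjusted p-values of genes are from limma.

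Before the data were examined, 24 gene lists were fixed, 3 of them markers of other cells that a preparation of oocytes could hold. The lists were spindle assembly checkpoint, kinetochore and centromere, cohesin, condensin, cell cycle control and APC/C, spindle motors and organisers, DNA damage response and repair, DNA methylation and imprint maintenance, chromatin modifying enzymes, nuclear-encoded oxidative phosphorylation, antioxidant defence, proteasome, cytosolic ribosomal proteins, and translation factors. The others were maternal mRNA storage and decay, dormant maternal mRNAs, oocyte-specific and maternal-effect genes, chaperones and unfolded protein response, autophagy and lysosome, apoptosis, cytokinesis and cortical machinery, cumulus and granulosa cell markers, ovarian stroma and endothelium markers, and blood and immune cell markers. Each gene was represented by its probe set with the highest mean signal among those with 1 gene. List genes without such a probe set were left out before the signal filter. Many ribosomal protein genes were lost in this way: 44 were matched, of which 41 were kept. Each list was compared with the other genes by limma's camera with a preset correlation of 0.01, adjusted over the 24 lists within each contrast. Camera with a correlation estimated for each list was run beside it.

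Genes were named by a rule fixed before the data were examined. It took the 6 largest rises and 6 largest falls among changed genes whose 2 groups did not overlap (for the difference between stages, without that condition). It also took up to 2 members of each list that rose and 2 that fell, by smallest adjusted p, and 20 genes fixed by name. All genes of the first part are named below, and members of lists that passed the list test or are described. Of the 20 fixed genes, 18 were among the genes kept; Rec8 and Ccnb1 were not. The 9 cumulus and granulosa cell markers below the signal filter are listed with their signals in GV oocytes. Single stroma, endothelium, blood and immune cell markers were named after their values were seen. Where another probe set of a named gene changed in the opposite direction past the threshold, this is stated at its first change.

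Control ratios, array medians and marker scores of the age groups were compared within each stage by exact permutation tests, two-sided, over the 70 assignments of 8 arrays to 2 groups. Their smallest possible p is 0.0286. A marker score is the mean over the kept genes of a list of log2 signals centred per gene over the 16 arrays. Recovery was tested on simulated data with 200 changed probe sets: 45.3% of 1.5-fold and 85.9% of 2-fold age changes were called in GV oocytes, 43.8% and 67.7% in MII eggs. For the difference between stages 35.9% of 2-fold and 98.3% of 4-fold changes were called. Of the calls on simulated data, 3.3% were false for GV age, 6.3% for MII age, 7.8% for the difference, 6.1% for young and 2.8% for old maturation, against the 5% set. A random list of further genes was also given a small shift. Far more of the 22519 probe sets were called in the real data (5.81% for GV age, 21.22% for MII age, 64.53% for young maturation). Simulated probe sets also varied independently, in a single run per contrast. These shares therefore do not carry over to the real contrasts.

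The alternatives tried were other added constants, no filter or the upper 30% of probe sets, quantile normalization, median centring, no variance trend, fits of the compared groups alone, array weights and the replicate number as a block. Stricter thresholds, another choice of probe sets per gene, and leaving out each array in turn were also run. Alternatives chosen after seeing the data were averages or a random block of neighbouring replicates, leaving out old GV arrays 1 and 2, covariates for the beta-actin control ratio and for the cumulus marker score, and leaving out probe sets that can match several transcripts. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.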

Results

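Gene expression was profiled in GV oocytes, which are arrested in prophase of the first meiotic division, and in MII eggs, which have completed that division. The stated purpose was to follow expression at both stages with maternal ageing, from 6 to 66 weeks. There were 4 arrays each of young GV oocytes, old GV oocytes, young MII eggs and old MII eggs. The median signal per array lay between 28.2 and 34.1 and the highest between 6486 and 10395. The 100 strongest probe sets held 5.34% to 7.21% of the summed signal of an array.

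Stage separated the arrays far more than age. The first principal component carried 78.7% of the variance and parted GV oocytes from MII eggs, and the second carried 4.21%. Arrays of the same group correlated at 0.968 to 0.982, and the highest correlation between a GV and an MII array was 0.799. Old and young MII eggs lay apart on the second component, as the plot of principal components shows.

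**Figure D1:**
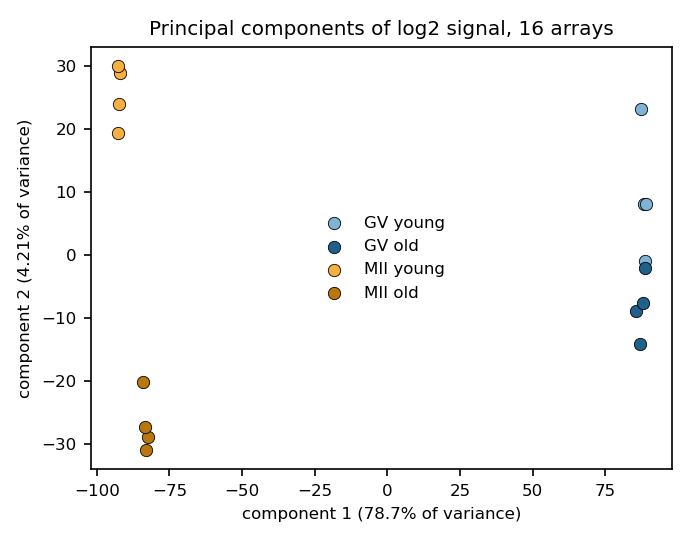
Each point is 1 of the 16 arrays, placed by the first (horizontal, 78.7% of variance) and second (vertical, 4.21% of variance) principal component of log2 signal, and coloured by stage and age. The GV arrays lie on the right and the MII arrays on the left, and old arrays lie below young arrays of the same stage.

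Control probe sets for RNA integrity also differed with age. The log2 ratio of 3' to 5' signal of beta-actin rose from 2.85 ± 0.10 in young to 3.92 ± 0.07 in old MII eggs (SD, n = 4, exact permutation p = 0.0286). In GV oocytes it went from 3.02 ± 0.26 to 3.45 ± 0.29 (SD, n = 4, exact permutation p = 0.0286). The Gapdh ratio went from 2.70 to 3.03 in GV oocytes (exact permutation p = 0.0286) and from 2.51 to 2.73 in MII eggs (exact permutation p = 0.0857). The 18S rRNA log2 ratio moved most, from -1.85 ± 0.32 to 0.50 ± 0.07 in MII eggs and from -0.76 ± 0.13 to -0.17 ± 0.18 in GV oocytes (SD, n = 4, exact permutation p = 0.0286 for both). Markers of cumulus and granulosa cells, which surround the oocyte in the follicle, were higher in old GV oocytes. Their mean centred log2 signal was 0.686 ± 0.359 against -0.078 ± 0.282 in young GV oocytes (SD, n = 4, exact permutation p = 0.0286), and the means of the MII groups differed by 0.005 (exact permutation p = 0.914).

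**Figure D2:**
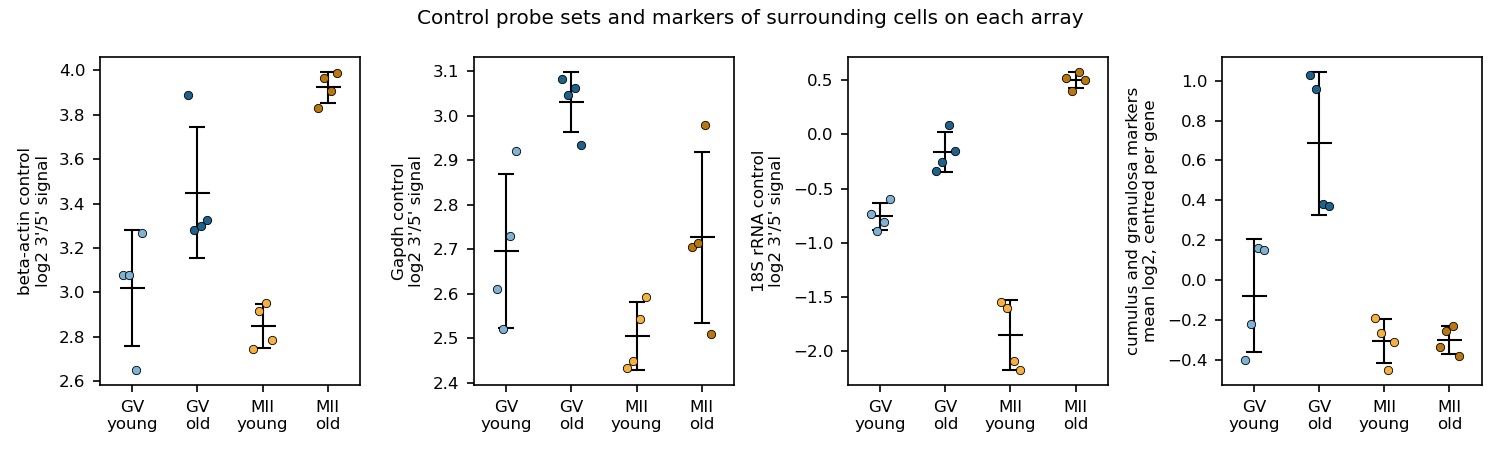
Points are the 16 arrays by group, with the mean and SD of each group of 4, for the log2 3' to 5' signal ratios of the beta-actin, Gapdh and 18S rRNA control probe sets and for the mean centred log2 signal of 12 cumulus and granulosa cell markers. The actin ratio is above 3.8 on each old MII array and below 3.0 on each young MII array, and the marker score is highest on the old GV arrays.

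Ageing of the GV oocyte was accompanied by lower transcripts of the general transcription factor Taf7 and the nuclear envelope protein Syne2, and by higher Gja1, a gap junction gene of granulosa cells. Taf7, a subunit of TFIID, fell from 552 ± 83.5 to 165 ± 35.9 (SD, n = 4), 3.29-fold (log2 change -1.72 ± 0.14 SE, adjusted p = 7.26e-07). Cttnbp2, which encodes a cortactin-binding protein, fell 3.35-fold from 149 ± 7.08 to 40.6 ± 7.87 (log2 -1.74 ± 0.14, adjusted p = 5.33e-07). The proteasome list was lower as a group, with 6 of its 40 kept members down and 0 up (camera adjusted p = 9.5e-05). Gja1 rose 6.97-fold from 110 ± 93.3 to 668 ± 397 (log2 2.80 ± 0.55, adjusted p = 0.00442).

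Of 22519 probe sets, 1309 (5.81%) changed with age in GV oocytes, 577 higher and 732 lower in old oocytes. They belong to 1097 genes, 16 of them called both ways; by the probe set chosen for each gene 348 rose and 380 fell. The median size of the changes was 1.37-fold, and 87 reached 2-fold. Over all probe sets the groups did not overlap in 3261 (14.48%), where chance would give 2.86%; 1151 of these were called. After Gja1 the largest rises with separate groups were Prrt4 (3.00-fold), Kctd14 (2.95-fold), the short-chain acyl-CoA dehydrogenase Acads (2.79-fold), the complement receptor C3ar1 (2.49-fold) and 1810064F22Rik (2.47-fold). The largest falls after Cttnbp2 and Taf7 were the extracellular matrix glycoprotein Tnc (2.83-fold), the microtubule-associated protein Eml5 (2.74-fold), Syne2 (2.61-fold) and the vesicular glutamate transporter Slc17a6 (2.52-fold). The Acads call was lost without any of 7 of the 8 GV arrays in turn (all but young array 4, adjusted p 0.0537 to 0.0761) and the C3ar1 call without 6 of them (all but young arrays 1 and 3, adjusted p 0.0685 to 0.125). With the cumulus marker score as a covariate, chosen after seeing the data, Kctd14 went from 1.56 ± 0.26 to 0.34 ± 0.25 (log2, SE, adjusted p = 0.709). Gja1 is itself part of the score. The other rises named here also lost their calls under it (log2 0.98 to 1.497, adjusted p 0.192 to 0.65), as did the falls of Tnc (-1.82, adjusted p = 0.137), Slc17a6 (-1.249, 0.343) and Eml5 (-1.205, 0.347), while Taf7, Cttnbp2 and Syne2 kept theirs. With the beta-actin ratio as a covariate the calls of Gja1, Prrt4, Acads, C3ar1, 1810064F22Rik, Tnc and Eml5 were lost (adjusted p 0.0515 to 0.313). With 4 times the added constant the calls held, with smaller log2 changes for genes of low signal: 1.02 for Prrt4, 1.009 for Acads, 0.736 for C3ar1, 0.887 for 1810064F22Rik, -1.023 for Tnc and -0.959 for Slc17a6.

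The proteasome, which degrades ubiquitinated proteins, was lower in old GV oocytes, and among the age contrasts it was the single list to pass with an estimated correlation as well (median log2 change -0.14, camera adjusted p = 9.5e-05, and adjusted p = 0.00547 with an estimated correlation). Of its 40 kept members, 6 fell over all genes tested, and 11 fell adjusted over the list alone. Psmd4, a ubiquitin receptor of the regulatory particle, fell 1.23-fold (log2 -0.30 ± 0.05, adjusted p = 0.00137), and the assembly chaperone Psmg1 fell 1.29-fold. Chaperones and the unfolded protein response were also lower (46 kept, 5 fell and 1 rose; 7 and 1 adjusted over the list alone; median -0.11, camera adjusted p = 0.00237). With an estimated correlation its adjusted p = 0.126. Pdia3, a disulphide isomerase of the endoplasmic reticulum, fell 2.08-fold and the chaperonin subunit Cct7 1.49-fold, while Hsp90b1 rose 1.31-fold.

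Oocyte-specific and maternal-effect genes were lower as a list (35 kept, 2 fell and 1 rose; 5 and 1 adjusted over the list alone; median -0.064, camera adjusted p = 0.000919), with adjusted p = 0.311 with an estimated correlation. Its falling members were Mos, the kinase that sustains meiotic arrest at metaphase (log2 -0.29 ± 0.06), and Cpeb1, a regulator of cytoplasmic polyadenylation (log2 -0.24 ± 0.06). The member that rose was Dppa3, which protects maternal imprints, by 0.28 ± 0.08. Cell cycle and APC/C genes fell as a list (42 kept, 5 fell and 1 rose; 6 and 2 adjusted over the list alone; median -0.036, camera adjusted p = 0.0285; adjusted p = 0.165 with an estimated correlation). The APC/C subunit Anapc16 fell 1.66-fold and the kinase Map2k1 1.24-fold. Without young GV array 1, the chaperone, oocyte-specific, cell cycle and cumulus marker lists all had an adjusted p of 0.0524. The cell cycle list also missed the threshold without young array 4 (0.0771) or old array 2 (0.0568). The cumulus marker score (by 0.764) and the actin, Gapdh and 18S log2 ratios (by 0.43, 0.34 and 0.59) moved between the same GV groups. With the marker score as a covariate the oocyte-specific list had a median of -0.022 (adjusted p = 0.448), chaperones -0.05 and cell cycle genes -0.042 (adjusted p = 0.212 for both), and the proteasome -0.125 (adjusted p = 0.00316). The Cpeb1 call was lost without young array 1 (adjusted p = 0.0553) and the Dppa3 call without any of 6 arrays (all but young array 1 and old array 4, 0.0588 to 0.144).

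Cumulus and granulosa cell markers were higher in old GV oocytes as a list, with 4 of 12 kept members up and 0 down (5 and 0 adjusted over the list alone; median 0.60, camera adjusted p = 0.0233). With an estimated correlation its adjusted p = 0.165. Besides Gja1, the inhibin subunit Inha rose from 157 ± 58.3 to 366 ± 167 (SD, n = 4) and the activin-binding protein Fst from 43.7 ± 24.7 to 129 ± 55.2. The 9 markers below the signal filter averaged, in young and old GV oocytes, 49.2 and 195 (Hsd3b1), 31.0 and 94.1 (Hsd17b1), 19.8 and 28.5 (Ptgs2), 13.3 and 23.3 (Vcan), 5.002 and 10.2 (Nr0b1), 2.51 and 4.29 (Amh), 11.6 and 12.5 (Ptx3), 15.3 and 13.6 (Wt1) and 13.4 and 7.57 (Tnfaip6). The Inha call was lost without young array 1 or 2 or old array 1 or 2 (adjusted p 0.0622 to 0.0901), and the list call also without old array 1 (0.0528) or 2 (0.0603). These last arrays carried the strongest marker signal, with scores of 1.03 and 0.961.

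In other lists of the old GV oocyte, the de novo DNA methyltransferase Dnmt3a fell 1.94-fold from 1149 ± 72.8 to 589 ± 48.3 (SD, n = 4, log2 -0.96 ± 0.09, adjusted p = 1.67e-06), and the insulator protein Ctcf fell 1.69-fold. The condensin subunits Ncapg and Smc2 fell 1.58-fold and 1.80-fold; another probe set of Ncapg rose. The DNA methylation list as such did not pass (camera adjusted p = 0.335), nor did condensin (0.912). Of the fixed genes, the checkpoint protein Mad2l1 (log2 -0.18, adjusted p = 0.0354) and the meiotic kinase Aurkc (-0.22, adjusted p = 0.0467) fell. The Mad2l1 call was lost without any of 6 GV arrays (all but young array 1 and old array 3) and the Aurkc call without any of 7 (all but young array 2), with adjusted p up to 0.113 and 0.148. No change passed the threshold for Bub1 (log2 0.33), Bub1b (-0.068), Cdc20 (0.052, with another probe set lower), Sgo1 (0.041), Sgo2a (0.050), Smc1b (-0.21), Smc3 (-0.094), Aurkb (0.085), Btg4 (-0.18), Dnmt1 (-0.040), Sirt1 (-0.29), Sod1 (-0.055), Gdf9 (-0.075) and Zp3 (-0.18). Bub1 was still higher on every old GV array (log2 signal 9.90 to 10.10) than on every young one (9.49 to 9.83). The spread used in its test includes MII arrays of low signal.

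The number of age calls in GV oocytes rested in part on single arrays: it was 851 without old array 1, 844 without old array 2, and 496 without both, an alternative chosen after seeing the data. Neighbouring GV arrays had similar marker scores, -0.404, -0.223, 0.163 and 0.151 on young arrays 1 to 4 and 1.03, 0.961, 0.381 and 0.372 on old arrays 1 to 4. With arrays 1 and 2 and arrays 3 and 4 averaged, also chosen after seeing the data, 418 calls were left, and with the same pairs as a random block 1157. Quantile normalization ended the calls of cell cycle (adjusted p = 0.202), oocyte-specific (0.0916) and cumulus marker lists (0.0592), and the upper 30% of probe sets those of cell cycle (0.137) and cumulus markers (0.845). Centring each array on its median moved the split from 44.1% higher to 27.4% higher. Every old GV array had a higher median signal than every young one (means 32.3 and 29.9, exact permutation p = 0.0286). The split thus depends on the scaling. In MII eggs the means of the medians were 32.3 in old and 31.5 in young (exact permutation p = 0.6). With the cumulus marker score as a covariate, chosen after seeing the data, 120 probe sets were called, and with the beta-actin ratio 448. Under the marker score the median change of the 1309 went from 0.459 (SE 0.101) to 0.445 (SE 0.167).

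**Figure D3:**
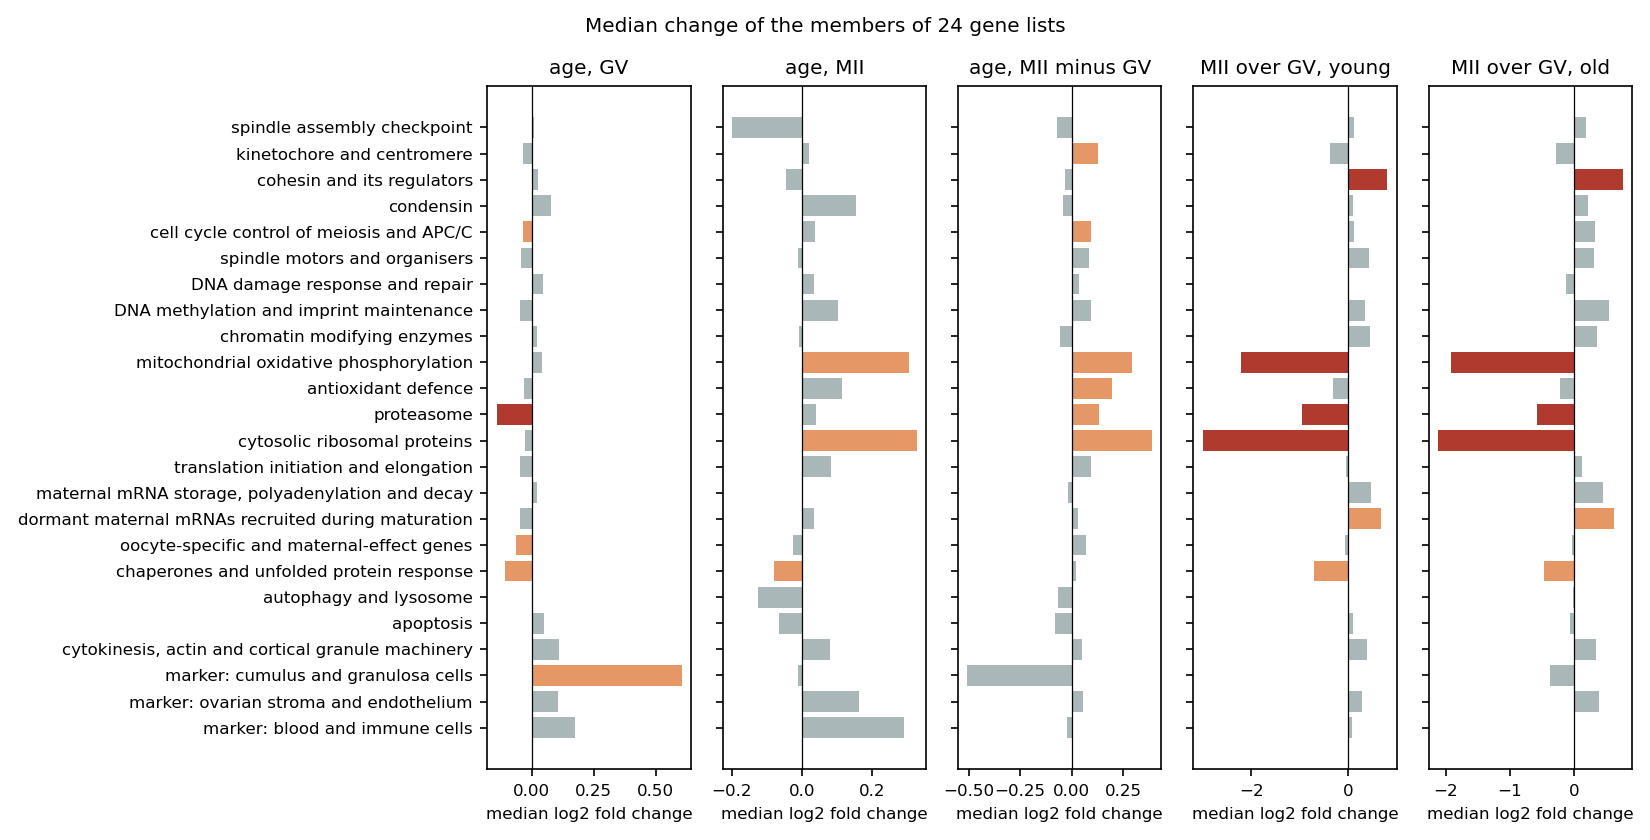
Bars give the median log2 fold change of the kept members of each of the 24 gene lists in the 5 contrasts. Dark red marks lists with a camera adjusted p under 0.05 with both the preset and an estimated correlation, orange those under 0.05 with the preset correlation only, and grey the others; the proteasome is the single dark red list of the age contrasts.

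Transcripts of the respiratory chain and of cytosolic ribosomal proteins had higher signals in old than in young MII eggs. The beta-actin control ratio separated the same groups completely, so age cannot be told apart from RNA quality or labelling here. Of 72 kept oxidative phosphorylation genes 33 rose and 2 fell, and of 41 kept ribosomal protein genes 20 rose and 0 fell (camera adjusted p = 5.55e-09 and 1.05e-08). With an estimated correlation the camera adjusted p = 0.204 for both. Many other ribosomal protein genes had no probe set assigned to 1 gene and were not tested. Mis18a, needed to load the centromeric histone, rose 3.25-fold from 528 ± 222 to 1622 ± 198 (SD, n = 4, log2 1.70 ± 0.19 SE, adjusted p = 4.14e-06). Its log2 signal on the young MII arrays ran in neighbouring pairs, at 8.28, 8.56, 9.49 and 9.52. If paired arrays share a pool, which the labels do not say, n = 4 counts too many replicates. The extracellular matrix glycoprotein Tnc fell 4.83-fold from 84.6 ± 13.5 to 14.1 ± 10.3 (log2 -2.27 ± 0.30, adjusted p = 2.18e-05). The DNA repair gene Brca1 fell 2.25-fold from 1657 ± 159 to 730 ± 34.3 (log2 -1.17 ± 0.09, adjusted p = 6.75e-08).

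In MII eggs 4779 probe sets (21.2%) changed with age, 2454 higher and 2325 lower, with a median size of 1.42-fold; 368 reached 2-fold. They belong to 3495 genes, 226 of them called both ways; by the chosen probe set 1475 genes rose and 1272 fell. Over all probe sets the groups did not overlap in 5192 (23.06%), against 2.86% by chance; 4006 of these were called. Besides Mis18a the largest rises with separate groups were Svbp, a partner of the tubulin carboxypeptidases (3.38-fold), 1110008P14Rik (3.38-fold), the potassium channel subunit Kcne4 (3.37-fold), the complement component C8g (3.13-fold) and Clasrp (3.00-fold). Besides Tnc the largest falls were Nat14 (3.20-fold), Thumpd1 (3.19-fold), Cttnbp2 (2.91-fold), Cuedc2 (2.90-fold) and the coatomer subunit Copg2 (2.83-fold). Thumpd1 went from 1032 ± 97.0 in young to 320 ± 32.4 in old MII eggs (SD, n = 4). The folds of genes with low signal depend on the added constant: with 4 times the constant the log2 change of Tnc was -1.489 instead of -2.271, that of C8g 0.98 instead of 1.647, that of Clasrp 1.057 instead of 1.583 and that of Cuedc2 -1.034 instead of -1.538, and Thumpd1 (-1.614) fell most of the genes named here.

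The oxidative phosphorylation list rose by a median log2 change of 0.31 (camera adjusted p = 5.55e-09; 39 rose and 2 fell adjusted over the list alone), with adjusted p = 0.204 with an estimated correlation. The cytochrome c oxidase subunits Cox6c and Cox6b1 rose 1.94-fold and 1.69-fold, and Cox6c went from 1276 ± 48.1 to 2482 ± 211 (SD, n = 4). Of the 2 members that fell, Sdha, a subunit of succinate dehydrogenase, decreased 1.21-fold. The ribosomal protein list rose by a median of 0.33 (camera adjusted p = 1.05e-08; 25 rose and 2 fell adjusted over the list alone), with adjusted p = 0.204 with an estimated correlation. Rps24 rose 2.88-fold from 116 ± 13.5 to 347 ± 64.5 and Rps29 2.01-fold. The beta-actin and 18S 3' to 5' log2 ratios moved with these lists, by 1.07 and 2.35 between young and old MII eggs. The kept stroma and endothelium markers moved too (by 0.207, exact permutation p = 0.0286), as did blood and immune markers (by 0.288, exact permutation p = 0.0571). Without the signal filter these marker shifts were smaller, 0.177 (exact permutation p = 0.0857) and 0.08 (exact permutation p = 0.2286). With the actin ratio as a covariate, chosen after seeing the data, the median was 0.056 for ribosomal proteins (adjusted p = 0.327) and 0.102 for oxidative phosphorylation (adjusted p = 0.0464).

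Chaperones were lower in old MII eggs, with 12 of 46 members down and 3 up, the same counts adjusted over the list alone (median -0.079, camera adjusted p = 0.0296; adjusted p = 0.241 with an estimated correlation). The inducible heat shock protein Hspa1b fell 2.28-fold and Cct7 1.71-fold. This call was lost without young MII array 4 (adjusted p = 0.0638) or old MII array 4 (0.0564), with the upper 30% of probe sets (0.0632), and with the actin ratio as a covariate (0.327). In the cell cycle list, which did not pass (0.425), 11 of 42 members rose and 5 fell: the kinase Cdk1 rose 1.93-fold and Plk1 fell 1.93-fold. In the kinetochore list (0.323), 12 of 45 rose and 4 fell, among them the centromere protein Cenpw up 2.42-fold. Among spindle genes Haus1, of the augmin complex, rose 2.59-fold and the microtubule polymerase Ckap5 fell 1.77-fold. The histone methyltransferase Kmt2b fell 2.30-fold, the proton pump subunit Atp6v1b2 2.31-fold and thioredoxin reductase Txnrd1 2.06-fold, and the mitochondrial superoxide dismutase Sod2 rose 1.63-fold.

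Members of the oocyte-specific list moved both ways in old MII eggs, 7 up and 8 down of 35 (camera adjusted p = 0.401). The zona pellucida gene Zp2 rose 1.54-fold, the maternal-effect gene Nlrp5 1.66-fold and Dppa3 1.30-fold, while the growth factor Bmp15 fell 1.42-fold. Dnmt3a rose 1.48-fold, but 2 other probe sets of it fell. Of the fixed genes, the cohesin subunit Smc3 fell 1.67-fold (log2 -0.74 ± 0.08, adjusted p = 2.47e-06), its protector Sgo2a 1.26-fold, the deacetylase Sirt1 1.30-fold and Mad2l1 1.15-fold. The checkpoint kinase Bub1 rose 1.48-fold (adjusted p = 0.0459) at low signal, 24.8 ± 9.57 to 38.9 ± 10.9 (SD, n = 4), and Aurkb 1.36-fold (adjusted p = 0.0482). The Bub1 call was lost without young MII array 1 or 4 or old array 1, 2 or 3 (adjusted p 0.0689 to 0.168), and the Aurkb call without the same arrays or young array 2 (0.0642 to 0.178). Over all alternatives their adjusted p ranged from 0.0151 to 0.769 and from 0.00386 to 0.67. No change passed the threshold for Bub1b (log2 -0.035), Cdc20 (0.14, with another probe set lower), Sgo1 (-0.068), Smc1b (0.28), Aurkc (0.009), Mos (-0.078), Btg4 (0.053), Dnmt1 (-0.023), Sod1 (0.078, with another probe set lower), Gdf9 (-0.034) and Zp3 (0.19).

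With the beta-actin ratio as a covariate, chosen after seeing the data, 25 of the 4779 probe sets were still called. The median change of the 4779 went from 0.51 (SE 0.108) to 0.38 (SE 0.247), and 91.7% kept their sign; Sirt1 (log2 0.090) and Dppa3 (-0.052) did not. The calls of the 12 genes given above with the largest rises and falls were lost (adjusted p 0.0706 to 0.613). The covariate follows the age groups, which widens the errors.

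The age effect differed between the stages for single genes such as Gja1, Taf7 and Dnmt3a and for transcripts of the respiratory chain. Gja1 had the largest difference, with an age effect in MII eggs minus that in GV oocytes of -3.75 ± 0.77 (log2, SE, adjusted p = 0.0031). Its signals in MII eggs were near the floor, 24.1 ± 10.2 in young and 9.79 ± 6.3 in old (SD, n = 4). Gja1 is also a cumulus and granulosa cell marker, for which cells carried over with GV oocytes are a candidate source. Taf7 fell with age in GV oocytes and went from 378 ± 34.2 to 501 ± 74.8 (SD, n = 4) in MII eggs, a difference of 2.11 ± 0.20 (adjusted p = 2.42e-06). Dnmt3a fell with age in GV oocytes and rose in MII eggs, a difference of 1.52 ± 0.12 (adjusted p = 6.18e-07), with 2 of its other probe sets opposite. Oxidative phosphorylation had 26 of 72 members with a more positive and 0 with a more negative age effect in MII eggs (camera adjusted p = 6.71e-09; adjusted p = 0.0543 with an estimated correlation).

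The test of the difference passed for 2532 probe sets, 1328 more positive and 1204 more negative in MII eggs. They belong to 1942 genes, 82 of them called both ways; by the chosen probe set 753 were more positive and 640 more negative. The largest positive differences were Kcne4 (log2 2.44), Taf7, the prefoldin subunit Pfdn1 (1.92), Fam229b (1.84), Mis18a (1.78) and the centrosomal protein Cep135 (1.76). The largest negative ones after Gja1 were Fst (-2.32), Prrt4 (-1.96), Acads (-1.88), the calcium channel partner Fkbp1b (-1.75) and Kctd14 (-1.72). The Acads call was lost without any of 12 of the 16 arrays (all but young GV arrays 3 and 4, young MII array 3 and old MII array 2; adjusted p 0.0528 to 0.0726). The Fkbp1b call was lost without young GV array 1 or 2, old GV array 4, young MII array 1 or 2, or old MII array 1 or 2 (adjusted p 0.0519 to 0.0653). With the cumulus marker score as a covariate the difference for Kctd14 was -0.504 (adjusted p = 0.443); Gja1 and Fst are part of that score. With 4 times the added constant the differences were smaller for genes of low signal, such as -2.952 for Gja1, -1.677 for Fst, 1.727 for Kcne4 and 1.17 for Fam229b, all still called.

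All 6 lists that passed had a more positive age effect in MII eggs. They were ribosomal proteins (14 of 41 members up and 0 down; 20 and 0 adjusted over the list alone; median 0.39, camera adjusted p = 1.25e-10), oxidative phosphorylation (29 and 0 adjusted over the list alone; median 0.29, 6.71e-09) and the proteasome (11 of 40 up, 1 down; 12 and 4 over the list alone; median 0.13, 0.015). The others were kinetochore genes (7 of 45 up, 2 down; 10 and 2 over the list alone; median 0.13, 0.0165), cell cycle genes (7 of 42 up, 2 down; 11 and 4 over the list alone; median 0.095, 0.0305) and antioxidant defence (4 of 33 up, 1 down; the same over the list alone; median 0.19, 0.0372). With an estimated correlation the adjusted p = 0.103 for cell cycle genes and 0.0543 for the other 5. Antioxidant defence was lost without young GV array 3, old GV array 2, any of young MII arrays 1 to 3 or old MII arrays 1 and 3 (adjusted p 0.0519 to 0.0647). The upper 30% of probe sets and quantile normalization ended the calls of kinetochore genes (0.0541 and 0.0615), cell cycle genes (0.0688 and 0.0914) and antioxidant defence (0.11 and 0.0615). The cell cycle call was lost without young GV array 4 (0.0541) or young MII array 2 (0.0557). Among members, Cox6c differed by 0.86, Cycs by 0.54, Rps24 by 1.39, Psma4 by 0.74, Cdk1 by 1.17 and Cenpw by 0.96. The actin control ratio rose with age by 0.43 in GV oocytes and by 1.07 in MII eggs; 670 probe sets passed with it as a covariate and 747 with the cumulus marker score.

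Across probe sets, which are not independent replicates, the age effects of the stages correlated weakly (Pearson r = 0.162, jackknife SE over arrays 0.0808; Spearman 0.168). They share no arrays, but both tests of a probe set use the same estimate of its spread. A probe set with a small spread is thus more easily called at both stages, and some genes have several probe sets. The Fisher tests below ignore both points, so their p-values do not measure shared age effects alone. Higher calls of both stages shared 177 probe sets against 62.9 for independent lists (Fisher's exact p = 2.52e-39), and lower calls shared 240 against 75.6 (Fisher's exact p = 6.58e-64). Among the shared falls were Tnc, Cttnbp2, Cct7 and Mad2l1, and among the shared rises Dppa3 and the imprint regulator Zfp57. The Zfp57 call in GV oocytes was lost without young array 1 or 2 or old array 1 or 3 (adjusted p 0.0516 to 0.0891). Probe sets lower in old GV oocytes and higher in old MII eggs numbered 122 against 79.8 (Fisher's exact p = 1.66e-06), and 51 against 59.6 went the other way (Fisher's exact p = 0.267).

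**Figure D4:**
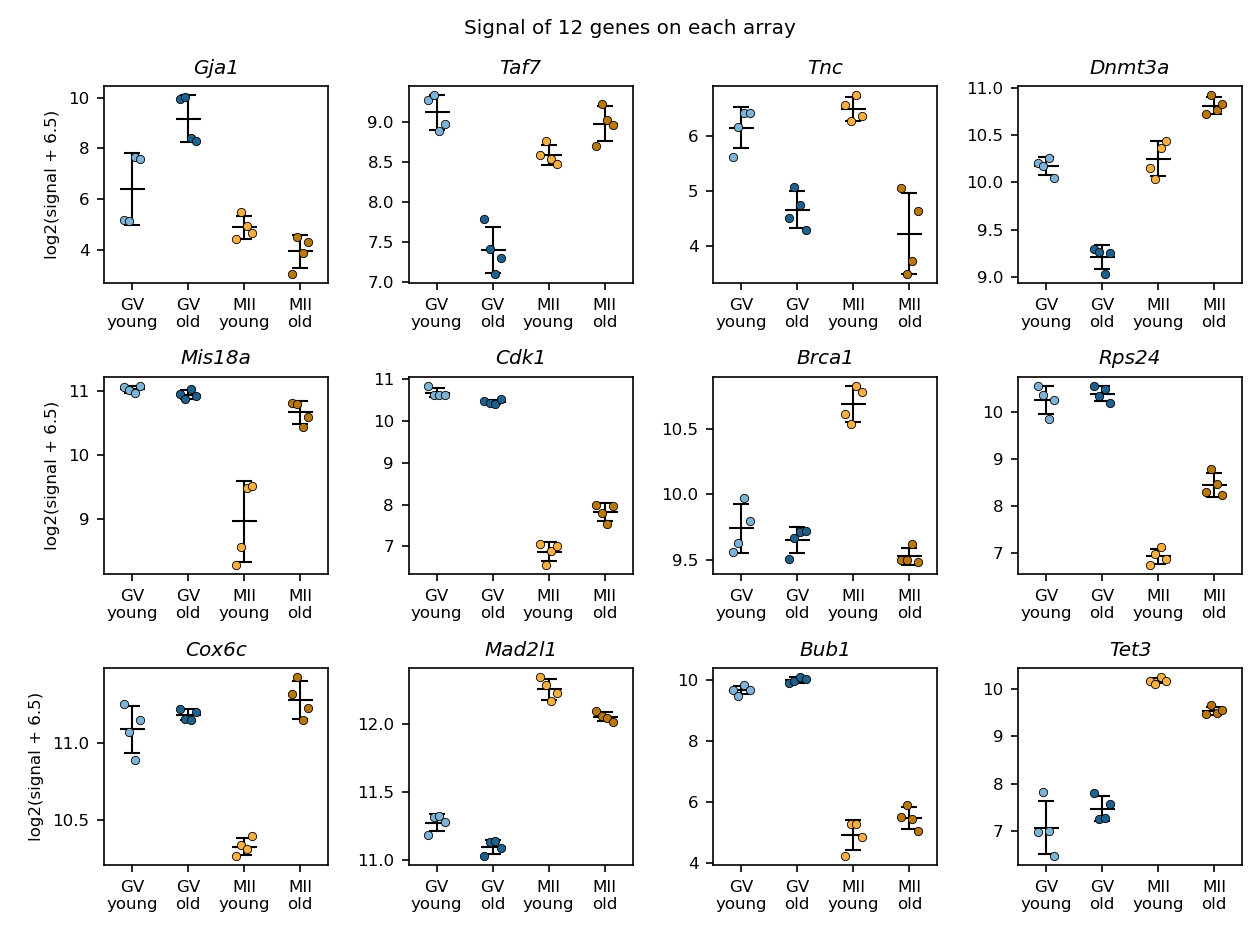
Points give log2 of signal plus 6.5 on each array for 12 named genes, with the mean and SD of the 4 arrays of each group. Gja1 is highest in old GV oocytes, Taf7 and Dnmt3a are lowest there, Tnc is lower in old samples of both stages, and Mis18a, Cdk1, Rps24 and Cox6c are higher in old than in young MII eggs.

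Maturation from the GV oocyte to the MII egg in young mice was accompanied by lower ribosomal protein and respiratory chain transcripts. Cohesin and its regulators were higher as a list. Of 41 ribosomal protein genes 37 fell and 0 rose, with a median decrease of 8.02-fold, and of 72 oxidative phosphorylation genes 62 fell and 5 rose, with a median of 4.63-fold (camera adjusted p = 3.36e-17 and 2.89e-17). Of 21 genes of cohesin and its regulators 17 rose and 2 fell (camera adjusted p = 0.00052). Rpl7 fell 38.7-fold from 1882 ± 61.2 to 42.4 ± 4.61 (SD, n = 4, adjusted p = 4.23e-19). The methylcytosine dioxygenase Tet3 rose 8.67-fold from 135 ± 58.4 to 1154 ± 47.3 (log2 3.12 ± 0.19 SE, adjusted p = 1.1e-11).

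In young mice 14531 probe sets (64.5%) differed between the stages, 8174 higher and 6357 lower in MII eggs; 6987 reached 2-fold. They belong to 8712 genes, 920 of them called both ways; by the chosen probe set 4455 genes rose and 3743 fell. Over all probe sets the groups did not overlap in 13432 (59.65%), against 2.86% by chance; 13050 of these were called. After Tet3 the largest rises with separate groups were Thumpd1 (6.45-fold), Tmie (5.46-fold), the histone demethylase Kdm6b (5.19-fold), Tanc2 (5.16-fold, with another probe set lower) and the vesicle-priming protein Unc13b (5.08-fold). Tmie had a signal of 6.79 ± 1.76 in young GV oocytes (SD, n = 4), and with 4 times the added constant its log2 change was 1.489 instead of 2.45, the smallest of these 6. The largest falls were the signalosome subunit Cops6 (124-fold), BC004004 (76.4-fold, with another probe set higher), the mitochondrial import subunit Timm17a (69.0-fold), Pdcd2 (60.5-fold), Zfp61 (59.8-fold) and the exosome nuclease Dis3l (57.9-fold). Signals of these genes in MII eggs were close to the floor, 3.52 ± 1.01 (SD, n = 4) for Cops6, so these folds and their order depend on the constant of 6.5. With 4 times the constant the log2 change of Cops6 was -5.409 instead of -6.95, and Timm17a (-5.508) fell most of the 6.

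Oxidative phosphorylation fell with a camera adjusted p = 2.89e-17 (0.0113 with an estimated correlation; 63 fell and 5 rose adjusted over the list alone). Ndufa2 fell 20.9-fold, and Ndufa10, also a subunit of complex I, rose 2.01-fold. Ribosomal proteins fell with a camera adjusted p = 3.36e-17 (0.0117 with an estimated correlation; 38 fell adjusted over the list alone), Rps4x among them by 21.8-fold. The proteasome (27 of 40 fell and 10 rose, the same over the list alone; median -0.94, camera adjusted p = 0.000149, 0.0102 with an estimated correlation) held Psmb4, down 18.9-fold, and Psmd1, up 3.31-fold. Chaperones were lower (27 of 46 fell and 13 rose, the same over the list alone; median -0.71, camera adjusted p = 0.00622; adjusted p = 0.102 with an estimated correlation). Cct5 fell 11.3-fold, and Hsp90b1 rose 2.94-fold with another probe set lower.

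The list of cohesin, which holds sister chromatids together, and of its regulators rose (17 of 21 up and 2 down, the same over the list alone, median 0.82, camera adjusted p = 0.00052, 0.0117 with an estimated correlation). Its regulators include genes that release or cleave cohesin. The cohesin loader Nipbl rose 4.41-fold, with 2 other probe sets lower, and separase, Espl1, rose 2.51-fold, while the meiotic subunit Smc1b fell (log2 -2.32 ± 0.30 SE) from 85.8 ± 12.6 to 13.3 ± 9.31 (SD, n = 4). Dormant maternal mRNAs, stored with short tails and recruited for translation in maturation, were higher (11 of 12 up and 0 down, the same over the list alone; median 0.69, camera adjusted p = 0.000645; adjusted p = 0.114 with an estimated correlation). Dazl rose 2.20-fold, Tpx2 2.33-fold and Orc6 1.81-fold. Whether these signals rose through the amount of mRNA or the length of its tails was not tested. In the cell cycle list (camera adjusted p = 0.971; median 0.13 and mean -0.32), 19 of 42 rose and 18 fell: the cyclin Ccna2 rose 2.08-fold and Cdk1 fell (log2 -3.81 ± 0.11 SE). Among spindle genes Tacc3 fell 21.1-fold, and the elongation factor Eef1a1 fell 12.1-fold.

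Of the fixed genes, Bub1 fell 27.1-fold while the checkpoint genes Mad2l1 (1.97-fold), Cdc20 (1.71-fold) and Bub1b (log2 0.59) rose. Sgo1, with another probe set lower, rose 2.11-fold, Sgo2a 1.62-fold, Smc3 1.79-fold, Aurkc 1.96-fold, Mos 1.33-fold, Sirt1 1.63-fold and Dppa3 1.37-fold. Sod1 fell 6.27-fold, with another probe set higher, Zp3 3.17-fold and Dnmt1 1.39-fold. Aurkb did not pass (log2 -0.27). Btg4 rose by 0.39 and Gdf9 by 0.44 on the authors' scale, but with quantile normalization their changes were -0.009 (adjusted p = 0.83) and 0.038 (adjusted p = 0.275). Over all probe sets the median change was 0.18 on the authors' scale and 0.44 after median centring. The share of higher calls went from 56.3% to 67.6%, so rises and falls are relative to the scaling, the smaller ones most.

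Maturation in old mice changed largely the same probe sets as in young mice. Ribosomal protein genes fell in 34 of 41 cases and rose in 1, with a median decrease of 4.35-fold, and oxidative phosphorylation genes fell in 60 of 72 and rose in 6, by a median of 3.78-fold (camera adjusted p = 5.71e-14 and 1.96e-14). The homeobox gene Hoxa7 rose 6.52-fold from 10.6 ± 1.98 to 105 ± 9.98 (SD, n = 4; log2 2.71 ± 0.23 SE, adjusted p = 2.4e-09). Ctcf rose 3.72-fold and Dnmt3a 3.02-fold, with another probe set of Dnmt3a lower.

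In old mice 14092 probe sets (62.6%) changed, 7710 higher and 6382 lower. They belong to 8450 genes, 934 of them called both ways; by the chosen probe set 4242 genes rose and 3732 fell. Over all probe sets the groups did not overlap in 13192 (58.58%), against 2.86% by chance; 12755 of these were called. After Hoxa7 the largest rises were Atp10b (5.75-fold), Zfp704 (5.43-fold), Tmed7 (5.19-fold), Tmie (4.82-fold) and the formin Diaph3 (4.72-fold). With 4 times the added constant the log2 change of Hoxa7 was 1.836 instead of 2.706, below Atp10b (2.083), Diaph3 (1.973) and Tmed7 (1.838). The largest falls were Arhgef16 (59.6-fold), BC004004 (56.1-fold, with another probe set higher), Cops6 (53.3-fold), Gm12338 (49.8-fold), Timm17a (49.8-fold) and Zfp61 (46.4-fold). Their signals in old MII eggs were low, from 10.8 ± 8.63 for Zfp61 and 17.3 ± 11.9 for Arhgef16 to 50.3 ± 6.75 for Timm17a (SD, n = 4), so these folds and their order depend on the added constant too. With 4 times the constant the log2 change of Arhgef16 was -4.957 instead of -5.898 and that of Zfp61 -4.394 instead of -5.535, and Timm17a (-5.218) fell most of the 6. The maturation changes of both ages correlated at 0.936 across probe sets (Spearman 0.879), and 12109 were called in the same direction at both ages and 91 in opposite directions. The median change was 0.14 on the authors' scale and 0.39 after median centring, and the share of higher calls went from 54.7% to 66.7%.

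The same 6 lists passed in old mice. Oxidative phosphorylation (61 fell and 6 rose adjusted over the list alone; camera adjusted p = 1.96e-14), ribosomal proteins (34 and 1 over the list alone; 5.71e-14), the proteasome (25 of 40 fell and 9 rose, the same over the list alone; median -0.57, 0.000921) and cohesin (17 of 21 rose and 2 fell, the same over the list alone; median 0.76, 0.000494) also passed with an estimated correlation (0.0148, 0.0244, 0.0148 and 0.0148). Chaperones (28 of 46 fell and 11 rose, the same over the list alone; 0.0047) and dormant mRNAs (11 of 12 rose and 0 fell; 11 and 1 over the list alone; 0.000362) had adjusted p = 0.0902 and 0.0984 with an estimated correlation. Bub1 fell 23.1-fold, Cdk1 6.23-fold, Ndufa2 18.3-fold and Rpl7 39.4-fold. Nipbl rose 3.20-fold, with 2 other probe sets lower. Of the other fixed genes, Mad2l1 (log2 0.95), Cdc20 (0.87), Bub1b (0.62), Sgo1 (0.97, another probe set lower), Sgo2a (0.31), Aurkc (1.19), Mos (0.62), Btg4 (0.62), Sirt1 (0.61), Gdf9 (0.48) and Dppa3 (0.56) rose. Sod1 (-2.52), Smc1b (-1.84), Zp3 (-1.29) and Dnmt1 (-0.46) fell, and Aurkb did not pass (0.090). The Smc3 change of 0.19 (adjusted p = 0.0496, with another probe set lower) was lost without any array but old GV array 4 (0.0555 to 0.13), and that of Gdf9 was -0.002 with quantile normalization (0.964).

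The other 13 lists passed in no contrast. Their smallest camera adjusted p-values came from the GV age contrast for spindle motors (0.221), cytokinesis and cortical machinery (0.16) and blood and immune cell markers (0.221), and from the MII age contrast for the spindle assembly checkpoint (0.401), condensin (0.689), autophagy (0.158) and stroma markers (0.413). Translation factors (0.0779) and apoptosis (0.36) came closest in the difference between stages, chromatin modifying enzymes (0.233) and mRNA storage and decay (0.0893) in young maturation, and DNA repair (0.745) and DNA methylation (0.154) in old maturation. In 29 of the 120 list tests the median or mean change had the opposite sign to the test, which compares a list with the other genes; 0 of these passed. Over all alternatives run, the adjusted p of the lists called for age in GV oocytes ranged from 6.23e-06 to 0.00547 for the proteasome, 2.24e-05 to 0.448 for oocyte-specific genes, 0.000249 to 0.212 for chaperones, 0.00362 to 0.269 for cell cycle genes and 3.67e-05 to 0.845 for cumulus markers. In MII eggs it ranged from 6.8e-12 to 0.204 for oxidative phosphorylation, 3.72e-16 to 0.327 for ribosomal proteins and 0.00729 to 0.327 for chaperones. For the difference between stages the highest values were 0.0543 for ribosomal proteins, oxidative phosphorylation and the proteasome, 0.0615 for kinetochore genes, 0.103 for cell cycle genes and 0.11 for antioxidant defence. In maturation only chaperones (up to 0.102) and dormant mRNAs (up to 0.114) exceeded the threshold under any alternative.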

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

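Apart from the counts over other splits of the arrays, the tests in this part were chosen after the results were seen.

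Cumulus and granulosa cell markers, and 577 probe sets in all, were higher in old GV oocytes; the strongest markers in old GV oocytes were Gja1 (668, against 110 in young), Nr5a2 (525, against 557) and Inha (366, against 157), 12 of the 21 markers passed the signal filter, and no sort or wash is given in the labels. Of these 12, Nr5a2, Cyp11a1 (98.5 in young, 87.1 in old) and Has2 (30.04 and 26.76) had lower means in old GV oocytes. RNA of these cells as the source of all the higher probe sets is argued against by their correlation with the marker score within groups, whose median over 569 probe sets was 0.012 (SE 0.042), although 3.12% of the 577 exceeded 0.8 against 1.2% of all probe sets. Of the 37 that rose at least 2-fold 8 exceeded 0.8, 6 of them probe sets of marker genes, and Kctd14 followed the score with a correlation of 0.949. For the markers themselves, cells carried over with the oocytes are a candidate source: between arrays of a group the markers varied together with a median correlation of 0.176, above 96.75% of 10000 random lists of like signal (95th percentile 0.153). Without old arrays 1 and 2, which had the highest marker signal, the list's median was 0.25 (adjusted p = 0.319, against 3.67e-05 to 0.845 over all its alternatives). Higher expression of these genes in the old oocyte itself stays open and was not tested.

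Oxidative phosphorylation and ribosomal protein lists were higher in old MII eggs, by a mean of 0.36 over 113 genes. A shift towards 3' ends in the same proportion to the actin ratio at both stages predicts a rise of 0.14 in old GV oocytes. The rise found was 0.010, a difference of -0.133 (SE 0.043). These values argue against such a shift only if the lists had no fall of their own with age in GV oocytes, which cannot be told apart here. A shift that follows the ratio within groups cannot be told apart from age: the mean of the lists followed it with a scaled slope of 0.631 (SE 0.369, and 0.319 to 0.801 when 1 array is left out), where 1 would account for the rise. The slope came from the GV arrays (0.713, SE 0.416); within the MII arrays, where the ratio varied little, it was -0.222 (SE 0.721), less than 2 standard errors from 1. The ratio as a covariate left medians of 0.102 and 0.056. Probe sets that match several transcripts are argued against too: without them both lists passed at the preset correlation, the larger adjusted p being 4.95e-05, with medians of 0.247 and 0.328. With an estimated correlation neither passed, without these probe sets (adjusted p = 0.0863 and 0.224) or with them (0.204 for both). Oocytes of the GV stage among the old MII eggs are argued against as the source of the whole rise. The lists need a share of 3.92%, but the 113 probe sets with a GV signal of at least 1000 that fall over 16-fold in maturation gave a median share of 0.88%, a ratio of 0.225 (SE 0.104) where 1 was predicted, and 8 of the 113 reached 3.92%. Of 12 pairs of cutoffs for signal and fall, 11 gave a ratio below 1 by more than 2 standard errors; the exception was a signal of at least 2000 with a fall over 4-fold (0.593, SE 0.25). Members of these lists were not left out of the 113. The 22 list members that fall over 16-fold gave 0.93%, close to the 113. The contrast thus lies between probe sets with large and with smaller falls, rather than between the lists and other probe sets. A smaller share of such oocytes, giving part of the rise, is not excluded. A slower loss of these transcripts in old eggs, as a biological difference by age, also stays open and was not tested.

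The beta-actin 3' to 5' ratio was higher on every old than on every young MII array. A loss of 5' signal of the same size in all transcripts is argued against by Gapdh. Its log2 ratio changed by 0.22 where the actin ratio changed by 1.07, a difference of -0.853 (SE 0.145). The 18S ratio rose by 2.35 in the same groups, and in GV oocytes actin (0.43), Gapdh (0.34) and 18S (0.59) rose too. A loss of 5' signal that differs in size between transcripts is not excluded. RNA quality or labelling as the cause of the age calls in MII eggs cannot be told apart from age: within groups, called probe sets followed the ratio with a scaled slope of 0.221 (SE 0.14), where 1 would account for them, but the ratio separates the age groups completely, so a covariate leaves few calls whatever the cause. A change with age of actin mRNA itself, in length or in its use of start and end sites, stays open and was not tested.

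Other splits of the arrays gave fewer calls than the real one for each count of probe sets, with 1 exception described below. For the 35 splits, 1 is the lowest count the test can give. The test treats the 4 arrays of a group as exchangeable, although neighbouring arrays resembled each other in some signals. It cannot address a batch shared by all arrays of a group. Of 35 splits of the arrays compared, only the real one gave as many calls for the age effect in GV oocytes (1309, highest other 13), in MII eggs (4779, highest other 12) and for maturation in young (14531, highest other 1) and old mice (14092, highest other 1), a count of 1 each. For the difference between stages 2 of 100 splits gave as many as 2532; the other gave 2699 and nearly exchanged the ages of the GV arrays, so that it measured the sum of the age effects, a structure of the samples. For the number of lists in the difference between stages, 4 of 100 splits reached 6 (highest other 6), which argues against chance only weakly. With an estimated correlation 0 lists passed there (smallest camera adjusted p = 0.0543). GV age had 5 lists (4 of 35 splits, highest other 6) and MII age 3 (2 of 35, highest other 3). Young maturation had 6 (8 of 35, highest other 6) and old maturation 6 (11 of 35, highest other 6). For these 4 counts chance is not excluded, and the number of splits alone cannot decide. Each other split that reached the real number is 1 of the 16 that exchange 1 array per group. Those keep part of the real difference. The 18 that exchange 2 hold no net difference between the groups, and they gave at most 4, 0, 1 and 1 lists. For GV age, then, camera at the preset correlation called up to 4 lists without an age difference, against 5 in the real split.

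The age effect differed between the stages, by the limma test of the difference itself, for 63 of the named genes and for 6 lists; values are log2, MII minus GV. Above 1 were Kcne4 (2.44), Taf7 (2.11), Pfdn1 (1.92), Fam229b (1.84), Mis18a (1.78), Cep135 (1.76), Syne2 (1.74), Haus1 (1.72), Clasrp (1.60), C8g (1.57), Svbp (1.57), Dnmt3a (1.52), 1110008P14Rik (1.46), Rps24 (1.39), Cdk1 (1.17), Smc2 (1.16), Pdia3 (1.06) and Anapc16 (1.01). Positive differences up to 1 were Cenpw (0.96), Rps29 (0.94), Ctcf (0.93), Ncapg (0.93), Cox6c (0.86), Diaph3 (0.80), Birc5 (0.77), Psma4 (0.74), Nlrp5 (0.72), Zp2 (0.69), Psmb4 (0.66), Eef1a1 (0.60), Sod2 (0.58), Cycs (0.54), Cox6b1 (0.53), Psmd4 (0.43), Ndufa10 (0.39), Orc6 (0.31) and Map2k1 (0.25). Below -1 were Gja1 (-3.75), Fst (-2.32), Prrt4 (-1.96), Acads (-1.88), Fkbp1b (-1.75), Kctd14 (-1.72), Cuedc2 (-1.59), Tanc2 (-1.58), Kmt2b (-1.50), Thumpd1 (-1.49), Copg2 (-1.45), Kdm6b (-1.35), 1810064F22Rik (-1.29), Txnrd1 (-1.16), Nat14 (-1.09), Brca1 (-1.08), Tet3 (-1.04) and Ckap5 (-1.01). Negative differences closer to 0 were Atp6v1b2 (-0.85), Plk1 (-0.81), Smc3 (-0.65), Bmp15 (-0.52), Nipbl (-0.46), Hsp90b1 (-0.43), Sgo2a (-0.39) and Espl1 (-0.29). Other probe sets of Dnmt3a, Anapc16 and Txnrd1 differed in the opposite direction. The median differences of the lists were 0.13 for kinetochore and centromere, 0.095 for cell cycle and APC/C, 0.29 for oxidative phosphorylation, 0.19 for antioxidant defence, 0.13 for proteasome and 0.39 for ribosomal proteins.

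Outside the main measurement, the control probe set for the 3' part of 18S rRNA was 4.28-fold higher in old than in young MII eggs (6027 ± 240 against 1407 ± 323, SD, n = 4, exact permutation p = 0.0286). The probe sets for its 5' part (4258 against 4971) and middle (7138 against 6163) differed by less. Both were also higher in young MII eggs than in young GV oocytes, 4971 against 682 for the 5' part and 6163 against 525 for the middle. What this difference between stages means for the maturation changes was not tested.

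Of 572 groups of 4 arrays, 32 held an array far from the other 3 for its range, where chance gives about 28.6. They included the actin log2 ratio on old GV array 1 (3.89), and the mean centred log2 signals of the kinetochore list on old GV array 2 (0.19), of the ribosomal protein list on young GV array 3 (1.03) and of the spindle motor list on old MII array 4 (-0.053). The others were log2 signals of named genes. On old GV array 1 Svbp (9.14) and on old GV array 3 Ctcf (8.74) and Smc1b (6.65) stood apart. On old GV array 4 Fkbp1b (6.07) and Kcne4 (6.2) and on old MII array 1 Cct5 (8.07) stood apart. On old MII array 2 Acads (6.48) and Zfp704 (5.85) and on old MII array 3 Brca1 (9.62), Bub1b (12.82), Dppa3 (12.62), Hsp90b1 (10.54), Nipbl (10.85) and Tmed7 (7.70) stood apart. On old MII array 4 Kctd14 (5.06), Map2k1 (12.05), Nlrp5 (11.33) and Tpx2 (10.72) and on young GV array 1 Cdk1 (10.84) stood apart. On young GV array 2 Ctcf (9.93), Rpl7 (10.95) and Tacc3 (11.28) and on young GV array 3 Svbp (8.44) stood apart. On young GV array 4 Smc2 (6.72), Tpx2 (9.58) and Zfp704 (6.04) and on young MII array 3 Acads (4.27) and Ctcf (10.61) stood apart.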

How the results depend on the processing

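The alternatives that averaged neighbouring arrays, left out old GV arrays 1 and 2, added covariates or left out probe sets that can match several transcripts were chosen after seeing the data. Under the alternatives chosen before the data were examined 4032 of 4188 values of changed genes kept their direction and side of the threshold, 154 lost the call and 2 reversed; of the list values 507 of 562 kept theirs and 55 lost the call. Of 883 values of genes not called, 869 stayed so. Under the added alternatives 719 of 893 gene values kept theirs, 171 lost the call and 3 reversed, and of the list values 72 of 85 kept theirs, 12 lost the call and 1 reversed. In the cases below the cause was not tested, except where fewer calls follow from a stricter threshold, fewer arrays, or a covariate that follows the age groups and widens the errors. For maturation, calls stayed within 1.5 times the counts given under each alternative run, between 11048 and 16545 in young and between 10971 and 15839 in old mice. For genes near the floor, signal over background limits the folds: the lowest mean signal tested was 29.7, close to the median of an array.

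Leaving out 1 array at a time gave 844 to 1229 calls for age in GV oocytes, 4013 to 4535 in MII eggs, 2071 to 2870 for the difference, 13914 to 14243 for maturation in young and 13532 to 13816 in old mice. The lists called ranged from 1 (without young GV array 1) to 8 (without young GV array 3) for GV age, with 3 without old GV array 2, from 2 to 3 for MII age, from 4 to 7 for the difference, and stayed at 6 for both maturation contrasts. The upper 30% of probe sets gave 3 lists for GV age and 3 for the difference, quantile normalization also 3 and 3, and an estimated correlation 1 for GV age, 0 for MII age and 0 for the difference, by limma's camera. At an unadjusted p under 0.05 the estimated correlation gave 4 lists for MII age and 6 for the difference, and the preset correlation 5 and 7. An adjusted p under 0.01 left 503 probe sets for GV age, 2984 for MII age and 1340 for the difference, and a fold of at least 1.5 left 407, 1825 and 1508. The replicate number as a block gave 1299, 4801 and 2496, 14541 and 14066, with 5, 3, 6, 6 and 6 lists; replicates of the same number did not pair, since 1 of 24 such pairs had a correlation of deviations over 0.1. The correlation of the age effects ranged from 0.105 to 0.195. Quantile normalization reversed Btg4 in young maturation (-0.009, adjusted p = 0.83) and Gdf9 in old maturation (-0.002, adjusted p = 0.964).

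Averaging arrays 1 and 2 and arrays 3 and 4 of each group left 418 calls for GV age, 3613 for MII age and 1409 for the difference. The same pairs of arrays as a random block gave 1157, 4580 and 2362 (consensus correlation 0.0379). The 18S 3' signal ran in such pairs in MII eggs, at 1686, 1687, 1154 and 1103 on young arrays 1 to 4. On old arrays 1 to 4 it was 5846, 5815, 6130 and 6317. If paired arrays share a pool, which the labels do not say, n = 4 counts too many replicates in each group. Without old GV arrays 1 and 2, GV age had 496 calls, 154 of them higher, and 3 lists. The actin ratio as a covariate left 448 calls for GV age, 25 for MII age and 670 for the difference, and reversed Sirt1 (0.090, adjusted p = 0.939) and Dppa3 (-0.052, adjusted p = 0.951) in MII eggs. The cumulus marker score left 120 calls for GV age, 25 of them higher (the median change of the 1309 went from 0.459, SE 0.101, to 0.445, SE 0.167), 1 list, and 747 calls for the difference, and reversed the cumulus list (-0.045, adjusted p = 0.67) and Inha (-0.18, adjusted p = 0.909) in GV oocytes; the score is the mean of the 12 list members, Inha among them, so the covariate holds the list's mean change at 0 by construction, and these values say nothing on stability.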

Other observations

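The tests in this part were chosen after the results were seen. Kept markers of cells other than cumulus had smaller mean shifts than cumulus markers in old GV oocytes (cumulus 0.764 higher). In old MII eggs their mean shifts were larger (cumulus 0.005 higher). The marker groups were not compared by a test. The cumulus mean in MII eggs averages members that moved both ways, such as Foxl2 (82.8 to 139) and Gja1 (24.1 to 9.79). Of its 12 kept members, 2 were called higher. Ovarian stroma and endothelium markers averaged 0.207 higher on the centred log2 scale in old than in young MII eggs (exact permutation p = 0.0286), with 1 of 9 kept members called, and 0.109 higher in old GV oocytes (exact permutation p = 0.514). The endothelial receptor Kdr, named after its values were seen, went from 135 ± 55.8 to 210 ± 38.4 in MII eggs (SD, n = 4), while Sparc went from 79.9 ± 21.9 to 69.5 ± 14.9. Blood and immune markers were higher by 0.248 in old GV oocytes (exact permutation p = 0.0857) and by 0.288 in old MII eggs (exact permutation p = 0.0571); H2-Aa, a class II histocompatibility gene also named after its values were seen, went from 248 ± 20.9 to 377 ± 40.1 in GV oocytes and from 91.6 ± 12 to 143 ± 13.7 in MII eggs (SD, n = 4), while Laptm5 went from 229 ± 49.8 to 218 ± 18.6 in MII eggs. These scores cover the markers that passed the signal filter. Over all 18 blood and immune markers the shifts were 0.183 in GV oocytes (exact permutation p = 0.1429) and 0.08 in MII eggs (exact permutation p = 0.2286). Over all 15 stroma and endothelium markers they were 0.189 (exact permutation p = 0.2) and 0.177 (exact permutation p = 0.0857). With 4 arrays a group, 0.0286 is the smallest p these tests can give.

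Age in the MII egg ran weakly against the change in maturation. With the maturation change and the age effect computed on separate young MII arrays, they correlated at -0.147 across probe sets (Spearman -0.133), and at -0.11 (Spearman -0.128) with the young MII arrays exchanged. Probe sets that fell over 16-fold in maturation were higher in old MII eggs by a median log2 of 0.22, those that fell 4 to 16-fold by 0.12, and those that rose over 4-fold lay at -0.15 (0.17, 0.14 and -0.13 with the arrays exchanged). Genes with several called probe sets often had calls in both directions: 226 of 684 genes (33.0%) for age in MII eggs, 16 of 79 (20.3%) in GV oocytes, and 920 of 2973 (30.9%) for maturation in young mice.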
